A study of Mus musculus with 15 samples.

How the data were processed

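Per the labels, RNA was extracted with the mirVana kit, amplified with a whole transcriptome amplification kit and labelled by a one-colour protocol. It was hybridised to Agilent mouse 4x44K arrays. Per the file headers, images were read with Agilent Feature Extraction 10.5.1.1, which subtracts background and removes spatial trends. The processed Cy3 signal it gives is an intensity on a linear scale per the file headers, with no normalization between arrays. The authors also deposited a normalized table. Its values are log2 intensity as the authors gave them, with 1 value per probe name. The normalization method was not stated. On 14 arrays this table had a Spearman correlation of 1.0000 with that array's own median spot signal, and on control 3 of 0.9903, across probes, which are not independent replicates.

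The values used here start from the processed signal. It was put on the log2 scale, and each array's 75th percentile was subtracted. Spots that Feature Extraction marked as non-uniform or population outliers were left out, which removed 0.293% of the gene values, and the spots of a probe were averaged. A probe was kept when it was well above background on at least 3 of the 15 arrays. Of 41174 probes on the array, 34908 had a gene symbol in the authors' table, and of these 29877 passed. Symbols of 4425 of 21538 genes were updated from a reference gene table, in which 19689 were found. A gene is represented by its probe with the highest mean over all arrays, and 7434 genes had at least 2 passing probes. Among the genes named in the text, Myc and E2f8 had probes called in opposite directions. The 4019 passing probes without a symbol were tested apart.

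The test was limma (version 3.58.1 in R 4.3.3), with 1 model for the 4 groups, 11 residual degrees of freedom and 5 comparisons. It is two-sided, with Benjamini-Hochberg adjustment over all 19339 genes tested, and a gene changed when its adjusted p was under 0.05. For a gene not well above background on any array of 1 group, and well above it on every array of the other, the change is given as a bound against the lowest signal well above background on the dim arrays.

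Gene lists were tested with camera, two-sided, with its preset correlation of 0.01 and again with a correlation estimated from the data, and adjusted over the 40 lists of a comparison. Counts of members are given over all genes and adjusted over the list alone. The lists were MYC activation targets, ribosome biogenesis, ribosomal proteins, glycolysis and lactate, hepatic glucose handling, glutamine and transamination, glutathione, nucleotide and one-carbon synthesis, cell cycle, DNA replication, hepatocyte secreted proteins, cytochrome P450 and detoxification, bile acid synthesis and transport, urea cycle and amino acid breakdown, fatty acid oxidation and ketogenesis, fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation, liver transcription factors, oncofetal and progenitor genes, the Dlk1-Dio3 imprinted region, p53 and cell cycle arrest, apoptosis regulators, unfolded protein and amino acid stress, hypoxia and angiogenesis, the acute phase, the interferon response, macrophages, T and NK cells, B and plasma cells, neutrophils, endothelium, stellate cells and fibroblasts, bile duct cells, erythroid cells, male-biased and female-biased liver genes, sex chromosome genes, clock genes, and immediate early and heat shock genes. Lists share members: 7 of the 25 MYC targets and 6 of the 35 ribosome biogenesis genes are also in another list.

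The lists, the model, the threshold and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 8 largest rises and the 8 largest falls among genes that passed, did not overlap between groups were well above background on 2 or more arrays of both groups and had a symbol that is not a clone, predicted or EST name. It adds the 4 largest bounds each way and 2 to 4 members of each list described, in order of adjusted p, or of size where no member passed. It always takes, among others, Myc, Mycn, Ldha, Pkm, Hk2, Pklr, Gls2, Gclc, Gclm, Afp, Alb, Igf2, H19, Mki67, Cdkn1a and Xist.

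The procedure was tested on simulated data with each gene's own mean and spread, with 100 genes changed at each size in the tumor group. Changes of 2-fold were recovered in 0% to 2% of genes and of 4-fold in 22% to 36%, with 1 to 3 false calls in the comparisons with tumor. With no group changed there were 0 calls. Genes were simulated as independent of each other, so this does not show how often lists would be called by chance on the real arrays. The alternatives tried were normexp background correction with an offset of 50 and quantile normalization, quantile normalization alone, median centring, the authors' table, no filter, and a filter for probes well above background on every array of at least 1 group. The others were slide or replicate number as a block, only the 2 groups compared, a trended robust variance, the mean of a gene's probes, and each of the 15 arrays left out in turn. Normexp used the median spot signal, since the files hold no mean signal. Below, normexp correction stands for this whole alternative, including its quantile normalization, so a shift under it is not due to background correction alone. Tables were read with the data.table package (version 1.17.8) and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.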

Results

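RNA levels were measured in mouse liver and liver tumours with Agilent whole-genome arrays, 1 Cy3-labelled sample per array. All mice were FVB/N, a laboratory strain. Control livers came from mice with the LAP-tTA transgene alone, in which a doxycycline-repressed activator is made in liver cells. The other mice also carried a MYC transgene that this activator switches on, so that MYC is made in the liver once doxycycline is removed from the food. Per the labels, doxycycline chow was given until the mice were over 8 weeks old. Pre-tumor livers were taken 4 to 5 weeks after its removal and held no tumor. Tumor nodules were taken 8 to 9 weeks after removal. Regression samples are liver tumor tissue from mice 8 to 9 weeks off doxycycline and then 72 hours back on it. There were 3 control, 4 pre-tumor, 4 tumor and 4 regression arrays. The labels do not say whether each array is a separate animal, and give no time off doxycycline for the controls.

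Each array held 43379 spots. The share of spots well above background ran from 46.4% (tumor 3) to 90.8% (pre-tumor 4), and the median processed signal from 6.78 to 71.3 intensity units in the same arrays. Pearson's r between arrays of 1 group, across genes (which are not independent replicates), lay between 0.837 and 0.935 in control, 0.880 and 0.944 in pre-tumor, 0.893 and 0.970 in tumor and 0.895 and 0.948 in regression. The first principal component held 35.7% of the variance and separated tumor and regression from control and pre-tumor arrays. The second held 17.4% and separated tumor from regression. The arrays were scanned on 1 day from 4 slides, and each slide held at most 1 array of each group.

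In all, 19339 genes were tested. Changes are log2 differences between group means with the SE of the limma model, from 4 arrays per group and 3 in control unless an n is given, and p values are adjusted over all genes tested or, for lists, over the 40 lists. List medians are given relative to the median change of all genes, which was −0.04 in pre-tumor against control, −0.18 in tumor against control, −0.13 in tumor against pre-tumor, −0.13 in regression against tumor and −0.25 in regression against control. For every list that was called, the mean, the median and the test had the same sign. "At least" marks a lower bound for a gene that was not well above background on any array of 1 group. Some fitted changes rest on signal near background, since 1 array of the dimmer group was well above it. In control these include Igf2, Mki67, Psph, Ggt1, Impdh1, Cenpa, Scd2, Pmaip1, Lum and Uty, in tumor Baat, Iigp1, Ifit1, Fpr1, Gpc3, Cd2 and the Myc probe with the lowest signal, and in regression Cyp7b1. The number of arrays limits the precision.

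The first comparison asks what 4 to 5 weeks of MYC expression change in liver before tumours appear. No single gene passed the limma test between pre-tumor and control liver. Among the largest differences was that of Cxcl10, an interferon-induced chemokine, at 4.13 ± 0.93 (adjusted p = 0.585). Alb, the serum albumin gene, differed by 0.01 ± 0.44 (adjusted p = 1). Afp, the fetal counterpart of albumin, was well above background on 2 of 4 pre-tumor arrays and 0 of 3 control arrays (adjusted p = 1). The cell division marker Mki67 differed by 0.75 ± 0.56 (adjusted p = 1).

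The limma count of 0 stands beside 505 genes with an unadjusted p under 0.05 and a smallest adjusted p of 0.116. The 505 ran over the alternatives from 305 with only 2 groups compared to 929 without control 1 and 1543 without the 4 high-E1A arrays. These arrays had the highest E1A spike-in probe signal. The smallest adjusted p was shared by Sergef at −2.39 ± 0.37 and Echdc3 at 2.54 ± 0.40, which were picked after their values were seen. The count was 11 after normexp background correction, 3 in the authors' table and 1 with a trended robust variance. Left-out arrays gave between 0 and 3 genes, the 3 without pre-tumor 2. In the 3 comparisons with tumor, simulated 4-fold changes were recovered in 22% to 36% of genes and simulated 2-fold changes in 0% to 2%. That simulation changed 100 genes at each size, in the tumor group alone. Recovery between pre-tumor and control was not simulated, and a count of 0 does not show that no gene changed. On all pre-tumor arrays and on no control array 11 genes were seen, led by Chac2 at least 2.19-fold, Cnp at least 1.75-fold, Nxpe2 at least 1.69-fold and Zfp429 at least 1.44-fold higher, all with adjusted p = 1. Of the other genes named in advance, Hk2 was well above background on 3 of 4 pre-tumor arrays and 0 of 3 control arrays. Gclc differed by 0.78 ± 0.45, Igf2 by 0.64 ± 0.56, H19 by 1.23 ± 0.61, Cdkn1a by −1.50 ± 0.56, Pklr by 0.53 ± 0.49, and Mycn by −0.34 ± 0.53. Ldha differed by −0.28 ± 0.38, Pkm by 0.25 ± 0.44 (n = 3 in pre-tumor), Gls2 by 0.13 ± 0.48, Gclm by −0.20 ± 0.48 and Xist by 0.31 ± 0.92. All of these had adjusted p = 1.

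By list, 10 of 40 were called with camera's preset correlation, 9 higher and 1 lower in pre-tumor liver, and 0 with an estimated correlation. Not among the 10 were MYC activation targets, ribosome biogenesis, DNA replication, the cell cycle and glycolysis. Over 27 alternatives MYC targets and ribosome biogenesis were each called under 2, DNA replication under 1, and the cell cycle and glycolysis under 0. In each of the 10 lists, 0 members passed over all genes. The endothelium list (vessel-lining cells) lay 0.53 above all genes (adjusted p = 0.000147, but adjusted p = 0.172 with an estimated correlation), with 1 of 19 members higher adjusted over the list alone. Tek, the angiopoietin receptor, differed by 1.50 ± 0.37 and Dnase1l3 by 1.14 ± 0.50. The unfolded protein and amino acid stress list lay below all genes (median −0.36, adjusted p = 0.000456, and adjusted p = 0.172 with an estimated correlation), with 1 member higher and 2 lower adjusted over the list alone. Atf3 differed by 2.56 ± 0.59 and Creld2 by −2.01 ± 0.63. Fatty acid synthesis genes lay 0.41 above (adjusted p = 0.00202, and adjusted p = 0.576 with an estimated correlation; 1 higher adjusted over the list alone), with Acss2 at 1.27 ± 0.79 and Insig2 at 1.20 ± 0.31. Cholesterol synthesis genes lay 0.51 above (adjusted p = 0.00265, and adjusted p = 0.777 with an estimated correlation), with Hmgcs1 at 1.38 ± 0.88 and Msmo1 at 1.32 ± 0.70. Stellate cell and fibroblast markers lay 0.31 above (adjusted p = 0.00265, and adjusted p = 0.379 with an estimated correlation), with Lum, a matrix proteoglycan, at 1.92 ± 0.61 and Pdgfrb at 1.51 ± 0.51. Nucleotide and one-carbon synthesis lay 0.41 above (adjusted p = 0.00575, and adjusted p = 0.379 with an estimated correlation), with Prps2 at least 1.19-fold higher and Mthfd1l well above background on 3 of 4 pre-tumor arrays and 0 of 3 control arrays. The sex chromosome genes lay 0.40 above (adjusted p = 0.0239, and adjusted p = 0.172 with an estimated correlation), with Uty at 1.52 ± 0.60 and Eif2s3y at 0.53 ± 0.35. Fatty acid oxidation and ketogenesis lay 0.35 above (adjusted p = 0.0382, and adjusted p = 0.792 with an estimated correlation), with Bdh1 at 0.84 ± 0.52 and Acadm at 0.79 ± 0.40. Apoptosis regulators lay 0.20 above (adjusted p = 0.0452, and adjusted p = 0.172 with an estimated correlation), with Birc2 at 1.65 ± 0.50 and Bcl2l1 at 1.52 ± 0.49. The interferon response list lay 0.27 above (adjusted p = 0.0499, and adjusted p = 0.792 with an estimated correlation), with 1 member higher adjusted over the list alone.

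The list calls rested on single arrays. Without control 2 there were 3 called lists and without pre-tumor 4 there were 16. The endothelium call ended without control 1 (adjusted p = 0.0599), as did that of stellate cells (0.272). The stress list ended without control 2 (0.120) and nucleotide synthesis without pre-tumor 3 (0.213). Fatty acid synthesis ended without control 2 or pre-tumor 3 (0.165 to 0.446), cholesterol synthesis without control 2, pre-tumor 2 or pre-tumor 3 (0.154 to 0.324), and the sex chromosome genes without control 1, control 2 or pre-tumor 3 (0.0512 to 0.154). Fatty acid oxidation ended without control 2, control 3, pre-tumor 2 or pre-tumor 3 (0.0688 to 0.859). Apoptosis regulators ended without control 1, control 2, pre-tumor 1 or pre-tumor 3 (0.0736 to 0.272). The interferon list ended without control 1, control 2, pre-tumor 1, pre-tumor 2, pre-tumor 3, tumor 2, tumor 3 or regression 3 (0.0506 to 0.525). Within the 3 slides that held both groups, list means ran from 0.40 to 0.56 for endothelium, but from −0.63 to 0.01 for the stress list, −0.35 to 1.60 for fatty acid synthesis and −0.64 to 1.17 for the interferon list. With slide as a block, 8 lists and 0 genes were called.

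The second comparison asks how established tumours differ from normal liver. Tumours held far more RNA of fetal liver genes and of cell division genes than control liver, and far less of the products of mature hepatocytes. Afp rose at least 1107-fold, and H19, an imprinted fetal non-coding RNA, rose by 10.77 ± 0.65 (1742-fold, n = 3 in both groups). Birc5, the mitotic survivin gene, rose by 5.94 ± 0.36 (61.4-fold) and Mcm6, part of the replicative helicase, by 5.55 ± 0.51 (46.7-fold). Mup1, a major urinary protein secreted by the liver, fell by 8.96 ± 1.09 (498-fold), and Saa2, a serum amyloid of the acute phase response, fell by 9.26 ± 0.93 (612-fold).

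Of 19339 genes, 3164 changed: 1810 rose and 1354 fell, of which 1784 and 1346 by at least 2-fold. The other largest rises were of Bex1 (7.98 ± 0.65, n = 3 in tumor), Bex3 (7.78 ± 0.59, n = 3 in tumor) and Bex4 (6.01 ± 0.54), a family of small brain-expressed X-linked genes. Psat1, an enzyme of serine synthesis (6.74 ± 0.51), and Top2a, the topoisomerase of dividing cells (5.86 ± 0.51), followed. These had adjusted p of 1.83e-06 or lower. The other largest falls were of Saa3 (−9.12 ± 0.65), Mup4 (−8.66 ± 0.92), the carboxylesterase Ces3b (−8.50 ± 0.55), Serpina3c (−8.41 ± 0.57), the orosomucoid Orm1 (−8.40 ± 0.87) and Mup3 (−8.27 ± 0.86), with adjusted p of 2.75e-05 or lower for all 8. Of genes seen in 1 group alone, 59 were higher and 63 lower in tumor. Bex2 rose at least 229-fold, Tmed6 at least 36.4-fold and Knstrn, a kinetochore gene, at least 24.4-fold. Cyp2a12 fell by at least 51.6-fold, Cyp7b1 by at least 42.7-fold and Aadat by at least 35.5-fold.

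**Figure D1:**
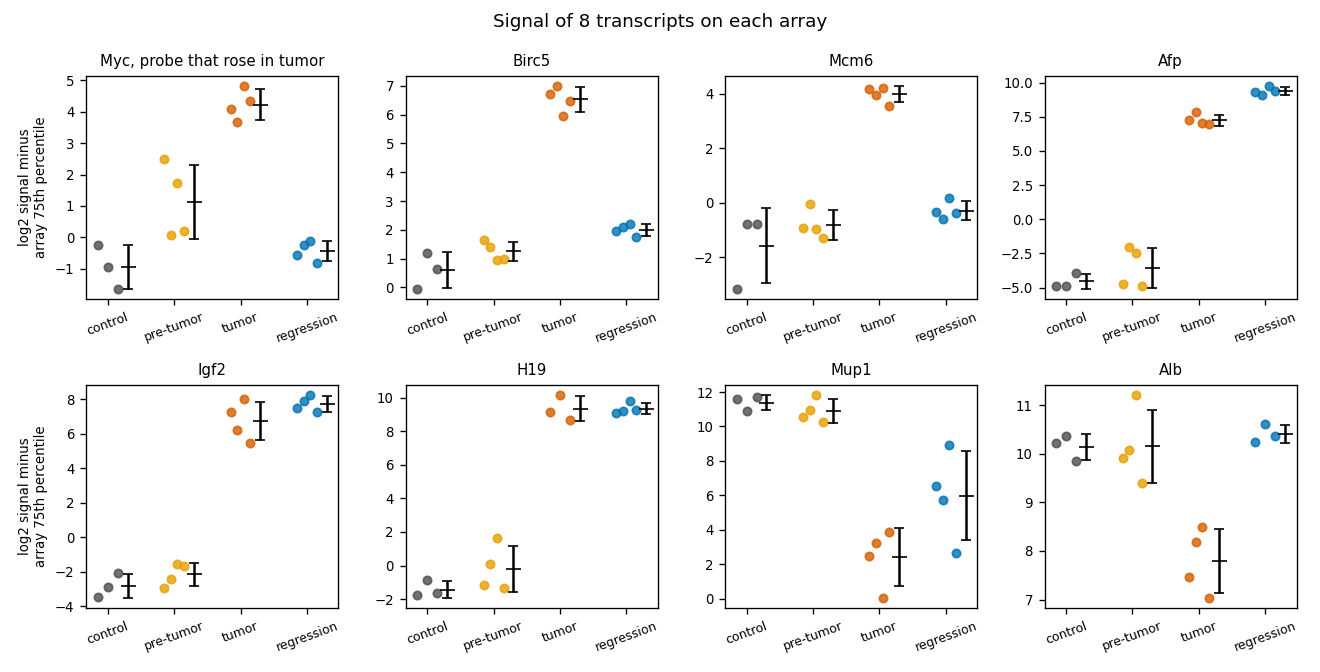
Scaled log2 signal of 8 genes on each array (dots) of the 4 groups, with bars at the group mean ± SD. Birc5 and Mcm6 are high in tumor and lower in regression, whereas Afp, Igf2 and H19 are high in both.

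Genes of growth and division rose together in tumor. Of 27 measured DNA replication genes 22 rose (24 adjusted over the list alone) and 0 fell, with a median 3.16 above all genes (adjusted p = 7.03e-21), among them the helicase genes Mcm7 (3.72 ± 0.30) and Mcm6. Of 32 cell cycle genes 22 rose and 1 fell (24 and 1 adjusted over the list alone; median 3.14, adjusted p = 5.22e-20), among them Birc5 and Cenpa, the centromere histone (4.78 ± 0.36). Mki67 rose by 4.50 ± 0.56. In nucleotide and one-carbon synthesis 19 of 24 rose (21 adjusted over the list alone; median 2.58, adjusted p = 1.54e-17), led by Mthfd1l at least 21.7-fold and Impdh1, of guanine nucleotide synthesis (4.73 ± 0.54). Of the 25 MYC activation targets 18 rose and 0 fell (20 and 1 adjusted over the list alone; median 2.18, adjusted p = 1.20e-13), with Npm1 at 2.99 ± 0.38 and Cdk4 at 2.98 ± 0.38. In glycolysis and lactate 10 of 17 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.73, adjusted p = 7.94e-08). Pkm, the pyruvate kinase of growing cells, rose by 4.32 ± 0.41, the lactate exporter Slc16a3 by 2.65 ± 0.39 and hexokinase Hk2 at least 5.71-fold. Ribosomal protein genes (24 of 28 rose, 27 adjusted over the list alone; median 1.93, adjusted p = 1.98e-16) were led by Rpl14 at 3.58 ± 0.42 and Rps20 at 1.96 ± 0.37, and their call was lost at adjusted p = 0.0895 with an estimated correlation. Ribosome biogenesis genes (25 of 35 rose, 28 adjusted over the list alone; median 1.97, adjusted p = 1.99e-16) were led by Npm1 and Dkc1 (2.58 ± 0.34), with adjusted p = 0.0551 with an estimated correlation. Of 25 oncofetal and progenitor genes 10 rose (10 adjusted over the list alone; median 0.83, adjusted p = 1.17e-06), led by Afp and by Igf2, the fetal growth factor (9.53 ± 0.56).

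Functions of mature liver fell. Of 24 cytochrome P450 and detoxification genes 23 fell (24 adjusted over the list alone) (median −4.40, adjusted p = 2.88e-28), led by the glucuronidation enzyme Ugt2b5 (−7.56 ± 0.44) and Aox3 (−7.35 ± 0.47). In bile acid synthesis and transport 13 of 16 fell (14 adjusted over the list alone; median −3.34, adjusted p = 1.94e-13), led by the uptake carrier Slco1b2 (−6.84 ± 0.46) and Baat (−6.64 ± 0.47). In the acute phase list 15 of 18 fell (17 adjusted over the list alone; median −5.03, adjusted p = 1.42e-17), led by Saa3 and Orm2 (−6.97 ± 0.58). Of 16 genes higher in male than female liver 15 fell (16 adjusted over the list alone; median −3.89, adjusted p = 1.68e-15), led by Cyp7b1 and Nudt7 (−4.32 ± 0.40). With an estimated correlation, 10 lists were called, namely these 4, DNA replication, cell cycle, nucleotide synthesis, MYC targets, glycolysis and oncofetal genes, at adjusted p from 0.000903 to 0.0346.

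The other lists that fell lost their call with an estimated correlation. Of 24 hepatocyte secreted proteins 21 fell (24 adjusted over the list alone; median −2.14, adjusted p = 1.05e-16, and adjusted p = 0.0895 with an estimated correlation), led by clotting factor F9 (−5.03 ± 0.40) and Itih1 (−4.00 ± 0.41); Alb fell by 2.34 ± 0.44. In the urea cycle and amino acid breakdown 19 of 23 fell (20 adjusted over the list alone; median −2.47, adjusted p = 1.24e-13, and adjusted p = 0.125 with an estimated correlation), led by Aass (−7.32 ± 0.66) and Tdo2, of tryptophan breakdown (−6.52 ± 0.66). In the interferon response 18 of 25 fell (21 adjusted over the list alone; median −1.98, adjusted p = 1.69e-10, and adjusted p = 0.0660 with an estimated correlation), led by Iigp1 (−6.61 ± 0.70) and Ifit1 (−5.56 ± 0.79). Hepatic glucose handling had 8 of 14 lower and 1 higher (9 and 1 adjusted over the list alone; median −1.63, adjusted p = 1.64e-05, and adjusted p = 0.167 with an estimated correlation), among them Fbp1 of gluconeogenesis (−6.92 ± 0.49). Of 17 genes higher in female than male liver 7 fell and 1 rose (8 and 1 adjusted over the list alone; median −1.19, adjusted p = 2.35e-05, and adjusted p = 0.0566 with an estimated correlation), led by Cyp2a4 (−7.40 ± 0.45) and Cyp3a41a (−5.31 ± 0.40). Fatty acid oxidation and ketogenesis had 9 of 21 lower (11 adjusted over the list alone; median −1.06, adjusted p = 9.41e-05, and adjusted p = 0.274 with an estimated correlation), among them Acaa1b (−3.72 ± 0.53). Liver transcription factors had 8 of 19 lower (8 adjusted over the list alone; median −0.86, adjusted p = 9.41e-05, and adjusted p = 0.0800 with an estimated correlation), led by Esr1 at least 2.64-fold lower and Onecut2 (−3.19 ± 0.48).

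Some called lists moved both ways in tumor. In the glutathione list 11 of 20 fell and 2 rose (13 and 2 adjusted over the list alone; median −1.20, adjusted p = 0.000730, and adjusted p = 0.234 with an estimated correlation). Ggt1, which breaks glutathione down outside cells, rose by 5.67 ± 0.49 and Gsta1, a glutathione transferase, fell by 3.19 ± 0.41. In fatty acid synthesis 9 of 19 fell and 2 rose (11 and 2 adjusted over the list alone; median −1.32, adjusted p = 0.00809, and adjusted p = 0.376 with an estimated correlation). Insig2 fell by 3.36 ± 0.31 while the desaturase Scd2 rose by 6.34 ± 0.74. In the unfolded protein and amino acid stress list 5 of 19 fell and 2 rose (5 and 2 adjusted over the list alone; median −0.59, adjusted p = 0.0430, and adjusted p = 0.274 with an estimated correlation). Asparagine synthetase Asns rose by 3.54 ± 0.36 and Dnajb9, a chaperone of the endoplasmic reticulum, fell by 3.22 ± 0.34. This list was not called without control 1, control 2, tumor 3 or tumor 4 (adjusted p from 0.0577 to 0.151), nor under 5 of the other alternatives (0.0551 to 0.0739). Fatty acid synthesis was not called with replicate number as a block (0.0595) or without the 4 high-E1A arrays (0.0767). Neutrophil markers (2 of 14 fell, 8 adjusted over the list alone; median −1.21, adjusted p = 0.00247, and adjusted p = 0.274 with an estimated correlation) were lower, among them the receptor genes Fpr2 (−3.56 ± 0.59) and Fpr1 (−3.28 ± 0.71, but −0.47 and not passing after normexp correction). Endothelial markers (4 of 19 fell, 4 adjusted over the list alone; median −0.57, adjusted p = 0.00911, and adjusted p = 0.197 with an estimated correlation) were also lower, among them Dnase1l3 (−2.75 ± 0.50) and Clec4g (−2.99 ± 0.59).

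The remaining 16 lists were not called in tumor against control. The glutamine and transamination list (adjusted p = 0.146) held 7 rising and 4 falling genes of 18 (7 and 6 adjusted over the list alone), with Psat1 and Psph, also of serine synthesis (5.16 ± 0.50), at the top. Gls2 differed by −1.07 ± 0.48 (adjusted p = 0.152). Macrophage markers (adjusted p = 0.131) had 5 rising and 2 falling genes of 20 (9 and 2 adjusted over the list alone): Cd68 rose by 2.96 ± 0.48 and Marco, of resident liver macrophages, fell by 3.46 ± 0.62. Stellate cell and fibroblast markers (adjusted p = 0.0546) had 5 rising and 1 falling of 22 (8 and 1 adjusted over the list alone), with the collagen genes Col3a1 at 3.11 ± 0.46 and Col1a2 at 3.17 ± 0.50. The stellate list was called under 5 alternatives of processing or model (adjusted p from 0.0230 to 0.0467) and without control 3, tumor 1, tumor 2, tumor 4, regression 1 or regression 4 (0.0174 to 0.0499), and the macrophage list without control 3 (0.0154). The p53 and cell cycle arrest list had an adjusted p of 0.0514, and was called with slide as a block (0.0467), with no filter (0.0395) and without tumor 1, tumor 2, regression 1 or regression 4 (0.0324 to 0.0473). Of the rest, erythroid cells had an adjusted p of 0.133, clock genes 0.155, T and NK cells 0.191, B and plasma cells 0.210, and hypoxia and angiogenesis 0.299. Bile duct cells had 0.425, apoptosis regulators 0.427, oxidative phosphorylation 0.447, immediate early and heat shock genes 0.516, cholesterol synthesis 0.544, the Dlk1-Dio3 imprinted region 0.617 and sex chromosome genes 0.958. Of the genes named in advance, Gclc had −1.38 ± 0.45 (adjusted p = 0.0460), which passed here but not with slide as a block (adjusted p = 0.138) and not without any 1 array other than pre-tumor 1, pre-tumor 2 or pre-tumor 3 (values from −1.48 to −1.18). It did not pass after normexp correction (−0.87) or with median centring (−1.06) either. Ldha differed by 0.64 ± 0.38, Mycn by −0.30 ± 0.53, Pklr by −0.98 ± 0.49, Gclm by −0.55 ± 0.48, Cdkn1a by −0.31 ± 0.56 and Xist by 0.48 ± 0.92, with adjusted p from 0.205 to 0.785.

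Of the 3164 genes, 3050 (96.4%) kept 1 sign in each of the 3 slides that held both groups, against 38.7% of all genes, and 2256 passed with slide as a block. Being called on the same arrays favours 1 sign, so the 96.4% is no separate support. Each called list kept 1 sign in these slides. The share of changed genes that were higher, 57.2%, ran over the alternatives from 46.9% without tumor 4 to 68.6% with median centring, so the balance of rises and falls depends on the processing and on that array. With genes not seen in 1 group set at their bound, and before the all-gene median is taken off, list medians went from 2.98 to 2.85 for DNA replication, 2.96 to 2.76 for the cell cycle, 2.40 to 2.37 for nucleotide synthesis and −4.07 to −3.92 for the male-biased list.

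The Myc gene itself was read by 3 probes that did not move together. The probe used for the gene differed by −1.10 ± 0.47 in tumor against control (adjusted p = 0.132 among probes). Another rose by 5.16 ± 0.54 against control (adjusted p = 7.74e-06) and by 3.10 ± 0.50 against pre-tumor (adjusted p = 0.000337), and fell by 4.66 ± 0.50 in regression (adjusted p = 2.78e-05); its pre-tumor value lay 2.06 ± 0.54 above control (adjusted p = 0.869). The remaining probe differed by −1.18 ± 0.45 in tumor against control (adjusted p = 0.0890), fell by 1.26 ± 0.41 against pre-tumor (adjusted p = 0.0435) and rose by 1.64 ± 0.41 in regression (adjusted p = 0.0126), but after normexp correction it moved by −0.09, −0.12 and 0.23 in these comparisons. At gene level, by the first of these probes, Myc differed by −0.43 ± 0.47 in pre-tumor against control, −0.67 ± 0.43 in tumor against pre-tumor, 0.67 ± 0.43 in regression against tumor and −0.44 ± 0.47 in regression against control, and passed in none of them.

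**Figure D2:**
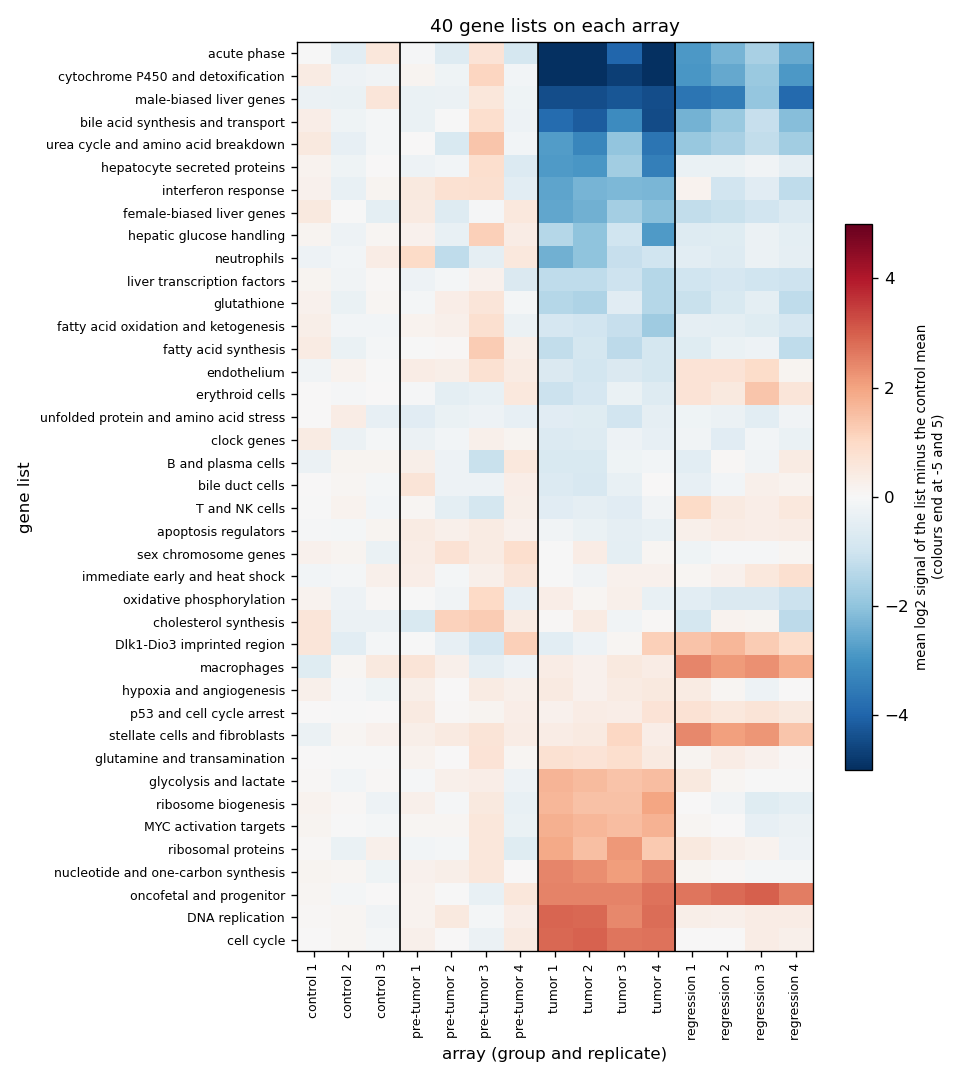
Mean scaled log2 signal of the 40 lists on each of the 15 arrays, minus the control mean, with colours ending at −5 and 5. Liver function lists are low in tumor and partly recovered in regression, and macrophage and stellate cell lists are highest in regression.

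The third comparison asks what separates tumours from MYC-expressing liver without a tumor. Many of the genes that stood apart were of the kinds seen against control. Both comparisons share the tumor arrays, so this likeness is no separate support, and it was not tested. Afp rose by 10.81 ± 0.55 (1796-fold), Igf2 by 8.89 ± 0.52 (474-fold) and Aurkb, a mitotic kinase, at least 6.68-fold. Cyp2e1, the ethanol-oxidising P450 enzyme, fell by 8.20 ± 1.23 (293-fold) and Pigr, the transporter of immunoglobulin A, fell at least 29.2-fold. Genes of the interferon response and of endothelium were lower in tumor than in pre-tumor liver.

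In all 3702 genes changed, 1942 higher and 1760 lower in tumor (1844 and 1722 by at least 2-fold). The largest other rises were of H19 (9.54 ± 0.61, n = 3 in tumor), Bex1 (7.31 ± 0.60, n = 3 in tumor), Psat1 (6.91 ± 0.47), Bex3 (6.47 ± 0.56, n = 3 in tumor), Bex4 (6.17 ± 0.50) and Scd2 (6.17 ± 0.69). Their adjusted p was 8.68e-06 or lower. The largest other falls were of Saa2 (−9.16 ± 0.86), Saa3 (−8.83 ± 0.60), Mup1 (−8.46 ± 1.01), Ces3b (−8.46 ± 0.51), Mup3 (−8.36 ± 0.86, n = 3 in pre-tumor), Mup4 (−8.25 ± 0.92, n = 3 in pre-tumor) and Orm1 (−8.09 ± 0.81). Their adjusted p was 1.77e-05 or lower. Of genes seen in 1 group alone, 9 were higher, with Knstrn at least 38.4-fold, Baiap2l2 at least 12.5-fold and Cdca7l at least 7.04-fold. A further 76 were lower, with Cyp2a12 at least 57.8-fold, Aadat at least 42.1-fold and Cyp7b1 at least 26.0-fold. Hk2 rose by 2.47 ± 0.50, Pkm by 4.07 ± 0.41 (n = 3 in pre-tumor) and Mki67 by 3.75 ± 0.52, whereas Alb fell by 2.35 ± 0.41 and Gclc by 2.16 ± 0.41. Pklr, the liver pyruvate kinase, fell by 1.51 ± 0.45 (adjusted p = 0.0273), but did not pass without pre-tumor 3, tumor 3 or tumor 4 (values from −1.42 to −1.02). It did not pass with median centring (−1.24) or without the 4 high-E1A arrays (−1.83) either. Ldha differed by 0.92 ± 0.36, Gls2 by −1.21 ± 0.44, Cdkn1a by 1.19 ± 0.52, Gclm by −0.35 ± 0.44, Xist by 0.17 ± 0.85 and Mycn by 0.04 ± 0.49, with adjusted p from 0.0723 to 0.974. Of these, Ldha passed without pre-tumor 3 (1.23), Gls2 without pre-tumor 2 (−1.57) and Cdkn1a without pre-tumor 1 (1.71).

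Of the 40 lists 23 were called, 8 higher and 15 lower in tumor, and 12 of them with an estimated correlation. The interferon response fell in 22 of 25 genes (23 adjusted over the list alone; median −2.28, adjusted p = 2.34e-13, and adjusted p = 0.0405 with an estimated correlation), led by Iigp1 (−6.90 ± 0.65) and Ifit1 (−5.62 ± 0.73). Endothelial markers fell in 9 of 19 (10 adjusted over the list alone; median −0.98, adjusted p = 1.70e-05, and adjusted p = 0.0485 with an estimated correlation), led by Dnase1l3 (−3.89 ± 0.46) and Clec4g (−4.02 ± 0.55). In the cell cycle list 24 of 32 rose and 1 fell (27 and 2 adjusted over the list alone; median 2.75, adjusted p = 2.16e-19), led by Birc5 (5.28 ± 0.33) and Cdk1. Of 27 DNA replication genes 22 rose (25 adjusted over the list alone; median 2.81, adjusted p = 2.16e-19), led by Mcm7 (3.31 ± 0.28) and Cdt1 (4.80 ± 0.41). All 24 of 24 P450 and detoxification genes fell (24 adjusted over the list alone; median −4.58, adjusted p = 2.10e-29), led by Ugt2b5 (−7.25 ± 0.40) and Aox3 (−7.27 ± 0.44). The other lists called both ways were nucleotide synthesis, MYC targets, glycolysis and oncofetal genes, which were higher, and bile acid genes, the acute phase and male-biased genes, which were lower. They had adjusted p of 1.29e-06 or lower, and adjusted p of 0.0405 or lower with an estimated correlation.

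With the preset correlation alone, 11 further lists were called. Ribosomal proteins (27 of 28 rose, 28 adjusted over the list alone; adjusted p = 0.0845 with an estimated correlation) and ribosome biogenesis (26 of 35 rose, 29 adjusted over the list alone; adjusted p = 0.0513 with an estimated correlation) were higher. The lists that were lower, each with its adjusted p with an estimated correlation, were secreted proteins (24 of 24 fell, adjusted p = 0.0903), the urea cycle (20 of 23, adjusted p = 0.102), and glucose handling (10 of 14, adjusted p = 0.111). So were fatty acid oxidation (9 of 21, adjusted p = 0.170), female-biased genes (8 of 17, adjusted p = 0.0513), and fatty acid synthesis (10 of 19 fell and 1 rose, adjusted p = 0.187). Also lower were glutathione (10 of 20 fell and 2 rose, adjusted p = 0.172) and liver transcription factors (6 of 19, adjusted p = 0.125). So were neutrophils (5 of 14, adjusted p = 0.304, and 0.0509 by the preset without the 4 high-E1A arrays). Within slides the neutrophil mean ran from −3.25 to 0.13, and the other called lists kept 1 sign. Of the 3702 genes, 3435 (92.8%) kept 1 sign in each of the 4 slides, against 28.4% of all genes, and 2938 passed with slide as a block. Here too the calls on the same arrays favour 1 sign. Over the alternatives, the 52.5% of changed genes that were higher ran from 40.6% without the 4 high-E1A arrays to 62.8% with median centring. Without tumor 4 it was 44.7%.

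The fourth comparison asks what 72 hours of renewed doxycycline, which switches MYC off again, changed in tumours. Lists of proliferation and ribosome biogenesis genes fell and detoxification, macrophage, endothelium, stellate and erythroid lists rose, each called both with the preset and with an estimated correlation. The oncofetal list was not called. The secreted protein and acute phase lists rose with the preset alone (adjusted p = 0.0548 for both with an estimated correlation). Birc5 fell by 4.53 ± 0.33 (23.1-fold) and Mcm6 by 4.26 ± 0.47 (19.2-fold). A2m, the protease inhibitor alpha-2-macroglobulin, rose by 5.63 ± 0.41 (49.4-fold) and Lcn2, an acute phase protein, by 6.32 ± 1.03 (80.1-fold). Afp rose further, by 2.13 ± 0.55 (4.38-fold; adjusted p = 0.0140), which did not pass after quantile normalization (1.63), while H19 differed by −0.00 ± 0.61 (n = 3 in tumor, adjusted p = 0.999).

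Of all genes 3254 changed, 1617 higher and 1637 lower in regression (1582 and 1587 by at least 2-fold). Other large rises were of Vnn3 (6.37 ± 0.64), Ces3b (5.69 ± 0.51), the haptoglobin gene Hp (5.64 ± 0.72, n = 3 in regression), Rdh7 (5.47 ± 0.55), Serpina3c (5.32 ± 0.52) and Serpina3k (5.20 ± 0.45). Other large falls were of the mitotic genes Aurka (−4.49 ± 0.56), Shcbp1 (−4.48 ± 0.40) and Ccnb1 (−4.41 ± 0.53), of Dut, which clears dUTP (−4.43 ± 0.32), of Sfmbt2 (−4.27 ± 0.37) and of Uhrf1, which maintains DNA methylation (−4.24 ± 0.28). These had adjusted p of 0.000620 or lower. Of genes seen in 1 group alone, 68 were higher, with Cyp2a12 at least 25.3-fold, Dkk3 at least 7.01-fold, Lum at least 6.85-fold and Apol7c at least 5.10-fold (0.55 and not passing after normexp correction). A further 26 were lower, with Bub1 at least 15.6-fold, Aunip at least 14.4-fold, Dtl at least 13.3-fold and Melk at least 12.6-fold. Alb rose by 2.61 ± 0.44 (n = 3 in regression), Pkm fell by 1.89 ± 0.38 and Mki67 by 2.36 ± 0.52. Hk2 fell by 1.78 ± 0.50 (adjusted p = 0.0217). This call ended without tumor 1, tumor 3 or regression 2 (values from −1.70 to −1.43) and without the 4 high-E1A arrays (−1.81). Ldha, lactate dehydrogenase, fell by 1.25 ± 0.36 (adjusted p = 0.0229), a call that ended with slide as a block (adjusted p = 0.0656), with median centring (−1.26) and without tumor 1, tumor 2, tumor 3, regression 2 or regression 4 (values from −1.22 to −1.12). Igf2 differed by 0.98 ± 0.52, Pklr by 0.47 ± 0.45, Gls2 by 0.30 ± 0.44, and Gclc by 0.56 ± 0.41. Gclm differed by −1.15 ± 0.44, Mycn by −0.79 ± 0.49, Cdkn1a by 0.66 ± 0.52 and Xist by −0.65 ± 0.85. Their adjusted p lay between 0.0969 and 0.794.

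Of the 40 lists 26 were called, 18 higher and 8 lower in regression, and 12 with an estimated correlation. The cell cycle list fell in 26 of 32 genes and rose in 1 (27 and 1 adjusted over the list alone; median −2.43, adjusted p = 4.76e-21), led by Birc5 and Aurkb, which fell at least 6.42-fold. DNA replication fell in 24 of 27 (26 adjusted over the list alone; median −2.52, adjusted p = 4.76e-21), led by Mcm7 (−2.83 ± 0.28) and Mcm6. Ribosome biogenesis fell in 29 of 35 (33 adjusted over the list alone; median −1.88, adjusted p = 7.99e-22), led by Dkc1 (−3.23 ± 0.32) and Nhp2 (−3.61 ± 0.40). Nucleotide and one-carbon synthesis fell in 23 of 24 (23 adjusted over the list alone; median −2.18, adjusted p = 2.94e-20), led by Mthfd1l (−3.43 ± 0.30) and Atic of purine synthesis, at least 3.77-fold lower. MYC targets fell in 21 of 25 with 1 higher (22 and 1 adjusted over the list alone; median −1.73, adjusted p = 6.88e-16), led by the spermidine synthase Srm (−3.77 ± 0.32) and Dkc1. Glycolysis genes fell in 12 of 17 (13 adjusted over the list alone; median −1.43, adjusted p = 3.29e-07), led by Slc16a3 (−3.28 ± 0.36) and the enolase Eno1 (−3.18 ± 0.46). Detoxification genes rose in 19 of 24 (19 adjusted over the list alone; median 2.36, adjusted p = 3.49e-18), led by Aox3 (5.03 ± 0.44) and Ugt2b5 (4.03 ± 0.40). The markers of other cell types rose beside them. Macrophage markers rose in 13 of 20 (13 adjusted over the list alone; median 2.09, adjusted p = 1.23e-10), led by the growth factor receptor Csf1r (2.51 ± 0.42) and Cd5l (2.12 ± 0.41). Endothelial markers rose in 11 of 19 (13 adjusted over the list alone; median 1.60, adjusted p = 9.01e-11), led by Stab1 (2.36 ± 0.32) and Cdh5 (2.22 ± 0.33). Stellate cell and fibroblast markers rose in 12 of 22 (12 adjusted over the list alone; median 2.01, adjusted p = 2.76e-08), led by Lum and Col14a1 (2.41 ± 0.33). Erythroid markers rose in 6 of 14 (6 adjusted over the list alone; median 1.24, adjusted p = 7.83e-06), led by Alas2 of haem synthesis (2.21 ± 0.43) and Rhd. Apoptosis regulators rose in 6 of 20 (6 adjusted over the list alone; median 0.79, adjusted p = 0.00274), led by Bcl2l11, which promotes cell death (2.49 ± 0.31), and Cflar, which restrains it (1.70 ± 0.35). These 12 lists were called with an estimated correlation at adjusted p of 0.0412 or lower.

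The other calls of this comparison were lost with an estimated correlation. Secreted proteins rose in 22 of 24 genes (22 adjusted over the list alone; median 2.39, adjusted p = 2.63e-21, and adjusted p = 0.0548 with an estimated correlation), led by F9 (4.17 ± 0.37) and Itih1 (3.91 ± 0.38). The acute phase list rose in 13 of 18 (14 adjusted over the list alone; median 3.19, adjusted p = 8.44e-13, and adjusted p = 0.0548 with an estimated correlation), led by Hp and Itih4 (3.26 ± 0.49). The interferon list rose in 12 of 25 (19 adjusted over the list alone; median 1.83, adjusted p = 1.93e-10, and adjusted p = 0.0575 with an estimated correlation), led by Iigp1 (4.71 ± 0.65) and Irf9 (1.68 ± 0.35). Ribosomal proteins fell in 25 of 28 (28 adjusted over the list alone; median −1.42, adjusted p = 5.35e-15, and adjusted p = 0.0920 with an estimated correlation). T and NK cell markers rose in 8 of 22 (9 adjusted over the list alone; median 0.93, adjusted p = 4.00e-06, and adjusted p = 0.0920 with an estimated correlation), led by the T cell receptor chain Cd3g (1.99 ± 0.30) and Cd2 (2.85 ± 0.50). Oxidative phosphorylation fell in 7 of 24 (9 adjusted over the list alone; median −0.80, adjusted p = 1.75e-05, and adjusted p = 0.327 with an estimated correlation), led by Cyc1 (−1.41 ± 0.36) and Atp5a1 (−1.27 ± 0.32, not passing with median centring or with probes averaged, at −1.28 and −1.01). Rising with adjusted p under 0.05 by the preset alone were also bile acid genes (8 of 16, adjusted p = 0.0579 with an estimated correlation), the urea cycle (10 of 23, adjusted p = 0.316 with an estimated correlation), and glucose handling (5 of 14, adjusted p = 0.228 with an estimated correlation). So did female-biased genes (8 of 17 rose and 1 fell, adjusted p = 0.0664 with an estimated correlation), male-biased genes (5 of 16, adjusted p = 0.269 with an estimated correlation) and neutrophils (1 of 14, adjusted p = 0.293 with an estimated correlation, and 0.0961 after normexp correction). Fatty acid oxidation (4 of 21 rose; adjusted p = 0.00630, and adjusted p = 0.415 with an estimated correlation) was not called without tumor 4 (adjusted p = 0.103). The Dlk1-Dio3 imprinted region (1 of 5 rose, Meg3 at 3.48 ± 0.38; adjusted p = 0.0332, and adjusted p = 0.269 with an estimated correlation) was not called without tumor 1, regression 1 or regression 2 (adjusted p from 0.0529 to 0.0613).

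The oncofetal and progenitor list was not called in regression against tumor (median 0.13, adjusted p = 0.446). Of its 25 genes 4 rose and 1 fell (4 and 3 adjusted over the list alone): Hmga1, a chromatin protein of growing cells, fell by 3.21 ± 0.45, and the glypican Gpc3 rose by 5.08 ± 0.88. Of the 3254 genes, 3132 (96.3%) kept 1 sign in each of the 4 slides, against 33.4% of all genes, and 2421 passed with slide as a block. Again the calls on the same arrays favour 1 sign. Each called list kept 1 sign in these slides. With genes not seen in 1 group at their bound and before centring, list medians went from −2.65 to −2.37 for DNA replication, −2.56 to −2.55 for the cell cycle and −2.31 to −2.27 for nucleotide synthesis.

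Of the 1810 genes raised in tumor, 1070 (59.1%) fell in regression, and of the 1354 lowered, 632 (46.7%) rose, so that 1702 genes moved back. By contrast, 82 raised genes rose again and 0 lowered genes fell again. Both comparisons share the tumor arrays, which gives opposite signs by chance. The covariance of the changes across genes was −0.72 against a simulated −0.14 (range −0.66 to 0.05). With the tumor arrays split between the comparisons it stayed between −0.73 and −0.41. Of the 1702 genes, 1491 did not pass between regression and control and 211 did, which does not show that the former were back at the control level. Of the pre-tumor changes, 0 genes were kept in tumor, since the pre-tumor count by limma was 0 with 505 genes at an unadjusted p under 0.05; the authors' table gave 2 and normexp correction 5. The covariance of pre-tumor and tumor changes was 0.11 against a simulated 0.19 (range −0.04 to 0.58).

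**Figure D3:**
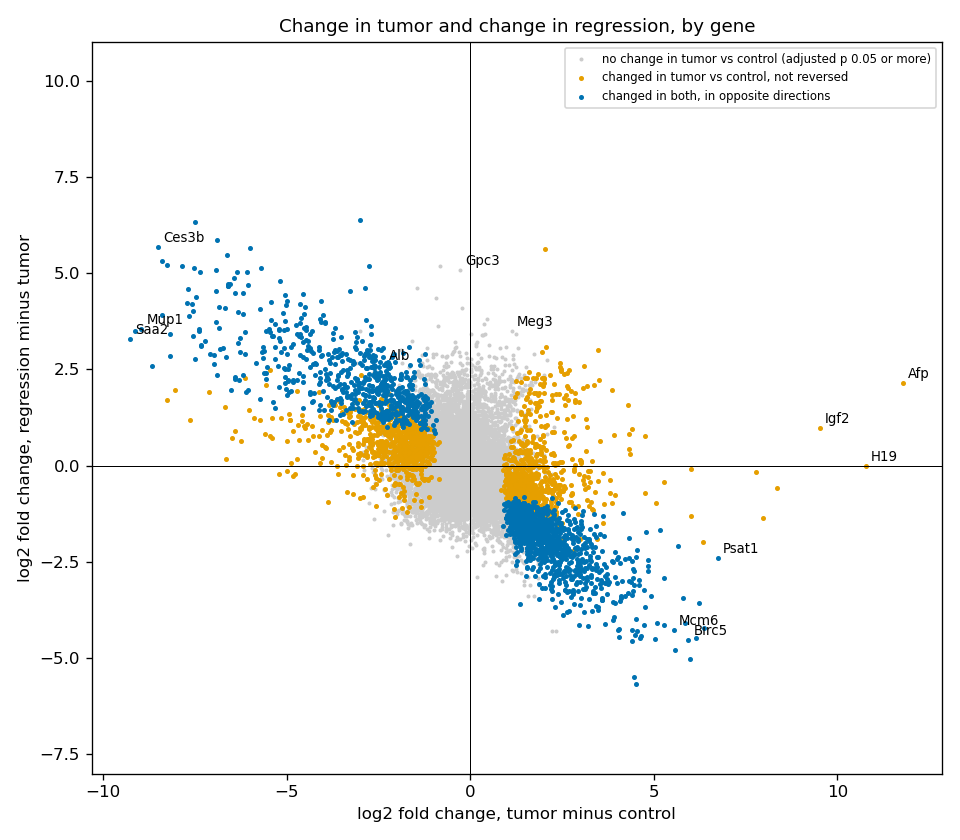
Log2 change of each gene in tumor against control (horizontal) and in regression against tumor (vertical), with the 1702 genes that moved back drawn apart. Shared tumor arrays alone tilt such a plot downwards.

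The fifth comparison asks what still separates tumor tissue from normal liver after 72 hours back on doxycycline. The oncofetal, macrophage and stellate cell lists were higher than in control liver with either correlation, and the detoxification list lower with the preset alone (adjusted p = 0.0669 with an estimated correlation). Afp was at least 4852-fold higher, and Igf2 rose by 10.51 ± 0.56, from a control level well above background on 1 of 3 arrays. Col3a1, a fibrillar collagen, rose by 5.71 ± 0.46 (52.2-fold), and Ms4a7, expressed in macrophages, by 6.47 ± 0.60 (88.6-fold). Mup3 fell by 6.56 ± 0.86 (94.2-fold), whereas Alb differed by 0.27 ± 0.47 (n = 3 in both groups, adjusted p = 0.779).

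Of all genes 1613 changed, 972 higher and 641 lower (972 and 640 by at least 2-fold). Other large rises were of H19 (10.76 ± 0.61), Bex3 (7.62 ± 0.56), Bex1 (6.63 ± 0.60), the cholesterol handling genes Soat1 (5.86 ± 0.68) and Abcg1 (5.83 ± 0.55), and the lysosomal membrane gene Cd63 (5.53 ± 0.55, n = 3 in both groups). Other large falls were of Mup4 (−6.08 ± 0.92) and Saa2 (−5.96 ± 0.99, n = 3 in both groups). Cyp2e1 fell as well (−6.07 ± 1.33, not passing at −5.79 without the 4 high-E1A arrays). Cyp2c38 fell too (−5.75 ± 0.65), as did Saa3 (−5.63 ± 0.65), Saa1 (−5.62 ± 0.54) and Cxcl13 (−5.43 ± 0.88). These had adjusted p of 0.00863 or lower. Of genes seen in 1 group alone, 101 were higher, with A2m at least 174-fold, Bex2 at least 152-fold and Hpgds at least 20.9-fold. A further 39 were lower, with Apol9a at least 12.5-fold, Ces1f at least 11.6-fold, Obp2a at least 9.21-fold and E2f8 at least 6.10-fold. Pkm rose by 2.43 ± 0.41. Mki67 rose by 2.14 ± 0.56 (adjusted p = 0.0277), a call that ended with slide as a block (adjusted p = 0.0880), with probes averaged (1.48) and without control 1, control 3, regression 2, regression 3 or regression 4 (values from 1.29, without control 1, to 2.27). Gclm fell by 1.69 ± 0.48 (adjusted p = 0.0396), a call that ended with slide as a block (adjusted p = 0.0981) and without control 1, control 3, pre-tumor 1, tumor 1, tumor 2, regression 1 or regression 4 (values from −1.69 to −1.23). It did not pass after normexp correction (−0.26), quantile normalization (−1.41) or median centring (−1.39), nor in the authors' table (−0.57). Hk2 was at least 1.66-fold higher and passed only with quantile normalization or median centring. Ldha differed by −0.60 ± 0.38, Pklr by −0.51 ± 0.49, Gls2 by −0.78 ± 0.48, Gclc by −0.82 ± 0.45, Mycn by −1.10 ± 0.53, Cdkn1a by 0.35 ± 0.56 and Xist by −0.17 ± 0.92, with adjusted p from 0.0848 to 0.934.

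Of the 40 lists 22 were called, 12 higher and 10 lower than control, and 4 with an estimated correlation. Oncofetal genes rose in 12 of 25 (13 with 1 lower adjusted over the list alone; median 2.02, adjusted p = 3.98e-10, and adjusted p = 0.00383 with an estimated correlation), led by Afp and Igf2. Macrophage markers rose in 13 of 20 and fell in 1 (13 and 1 adjusted over the list alone; median 2.62, adjusted p = 6.54e-12, and adjusted p = 0.0413 with an estimated correlation), led by Cd5l (4.41 ± 0.44) and Cd68 (4.61 ± 0.48). Stellate cell and fibroblast markers rose in 9 of 22 (12 adjusted over the list alone; median 1.92, adjusted p = 1.12e-11, and adjusted p = 0.0400 with an estimated correlation), led by Col3a1 and Col1a2 (5.23 ± 0.50). In the p53 and cell cycle arrest list 2 of 22 rose (3 adjusted over the list alone; median 0.71, adjusted p = 0.00274, and adjusted p = 0.0413 with an estimated correlation), namely Sesn1 (1.66 ± 0.33, but 1.27 and not passing with probes averaged) and Pmaip1, which promotes cell death (3.49 ± 0.73).

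The other calls against control were lost with an estimated correlation. Detoxification genes fell in 19 of 24 (21 adjusted over the list alone; median −2.32, adjusted p = 8.44e-14, and adjusted p = 0.0669 with an estimated correlation), led by Cyp2c29 (−3.70 ± 0.43) and Ugt2b5 (−3.53 ± 0.44). Male-biased genes fell in 12 of 16 (14 adjusted over the list alone; median −2.34, adjusted p = 4.79e-12, and adjusted p = 0.0661 with an estimated correlation), led by Cyp7b1 (−6.45 ± 0.60) and Nudt7 (−3.30 ± 0.40). The acute phase fell in 8 of 18 (median −1.36, adjusted p = 2.76e-06, and adjusted p = 0.252 with an estimated correlation). The urea cycle fell in 8 of 23 (median −1.31, adjusted p = 5.25e-06, and adjusted p = 0.389 with an estimated correlation), and bile acid genes in 6 of 16 (median −1.15, adjusted p = 5.19e-05, and adjusted p = 0.252 with an estimated correlation). Endothelial markers rose in 7 of 19 and fell in 1 (8 and 1 adjusted over the list alone; median 1.09, adjusted p = 0.000521, and adjusted p = 0.171 with an estimated correlation), led by Tie1 (2.31 ± 0.35) and Tek (2.18 ± 0.37). T and NK cell markers rose in 6 of 22 (adjusted p = 0.00283, and adjusted p = 0.320 with an estimated correlation). DNA replication genes rose in 2 of 27 with 1 lower (adjusted p = 0.00648, and adjusted p = 0.252 with an estimated correlation) and erythroid markers in 3 of 14 (adjusted p = 0.00648, and adjusted p = 0.252 with an estimated correlation). Liver transcription factors fell in 3 of 19 (adjusted p = 0.00376, and adjusted p = 0.252 with an estimated correlation). Glutathione genes fell in 5 of 20 with 2 higher (13 and 2 adjusted over the list alone; adjusted p = 0.00421, and adjusted p = 0.345 with an estimated correlation). Oxidative phosphorylation was called lower with 0 of 24 genes passing (median −0.52, adjusted p = 0.00126, and adjusted p = 0.591 with an estimated correlation).

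Against control, 6 calls ended with 1 array left out as well as with an estimated correlation. Female-biased genes (4 of 17 fell and 2 rose; adjusted p = 0.0128, and adjusted p = 0.279 with an estimated correlation) ended without control 1 (0.0600). So did immediate early and heat shock genes (4 of 21 rose and 1 fell; adjusted p = 0.0162, and adjusted p = 0.252 with an estimated correlation; 0.0825 without control 1), with Egr1 at 3.77 ± 0.66 and a range within slides of −0.14 to 0.93, where the other called lists kept 1 sign. The Dlk1-Dio3 region (2 of 5 rose, Meg3 at 4.61 ± 0.41 and Dlk1 at 3.58 ± 0.61; adjusted p = 0.0441, and adjusted p = 0.325 with an estimated correlation) ended without control 2, pre-tumor 3, pre-tumor 4, tumor 4 or regression 2 (0.0502 to 0.111). The cell cycle list (5 of 32 rose and 1 fell; adjusted p = 0.0446, and adjusted p = 0.302 with an estimated correlation) ended without control 1, control 3, pre-tumor 2, pre-tumor 4 or regression 3 (0.0501 to 0.0946) and with slide as a block (0.0556). Fatty acid oxidation (3 of 21 fell; adjusted p = 0.0446, and adjusted p = 0.709 with an estimated correlation) ended without control 1, pre-tumor 4, regression 3 or regression 4 (0.0502 to 0.186). Apoptosis regulators (3 of 20 rose; adjusted p = 0.0488, and adjusted p = 0.172 with an estimated correlation) ended without control 1, control 2, pre-tumor 2, pre-tumor 3, pre-tumor 4, tumor 4, regression 2, regression 3 or regression 4 (0.0501 to 0.115) and with slide as a block (0.0586). Of the 1613 genes, 1604 (99.4%) kept 1 sign in each of the 3 slides that held both groups, against 38.9% of all genes. The 1613 were called on these same arrays, so the 99.4% is no separate support. With slide as a block 990 genes passed and without regression 1 there were 1027. The share of changed genes that were higher, 60.3%, ran over the alternatives from 37.0% with replicate number as a block to 72.0% with median centring.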

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

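All the tests of the 3 patterns weighed in this part were chosen only after the result was seen, whereas the counts over other splits of the arrays were planned.

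In groups of 4 arrays, the highest or lowest array is marked as far from the others when its gap to the nearest one, over the whole range, is above Dixon's 95% value. Of 606 groups of values from named genes and lists, 39 were marked, where chance marks about 1 in 20 groups. Tumor 3 had more than any other array, 15: Aunip (0.936), Aurkb (0.870), Bdh1 (0.902), Bex4 (0.928), Birc2 (0.893), Hmga1 (0.924), Melk (0.890), Nhp2 (0.966), Orm2 (0.927), Pkm (0.858), Rpl14 (0.836), and the lists of cytochrome P450 and detoxification (0.857), glutathione (0.878), male-biased liver genes (0.912) and stellate cells (0.840). This array had the smallest share of spots well above background. Next came pre-tumor 3, with Asns (0.904), Eno1 (0.845), Itih1 (0.880), Pigr (0.922), Pklr (0.844), Serpina3k (0.852) and the male-biased list (0.874).

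The other arrays had fewer. Regression 3 was apart for Aadat (0.830), Aurkb (0.909), Psat1 (0.848) and Psph (0.924), regression 1 for Dkc1 (0.837), Hpgds (0.841) and Sfmbt2 (0.855), and regression 4 for Gpc3 (0.971). Tumor 4 was apart for Mki67 (0.863) and the oncofetal list (0.871), tumor 1 for Insig2 (0.840) and Irf9 (0.879), and tumor 2 for Cyp2c38 (0.875) and Xist (0.876). Pre-tumor 1 was apart for Cdkn1a (0.859) and Uhrf1 (0.878), and pre-tumor 2 for Atf3 (0.853).

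Pre-tumor liver and tumor nodules, which differ in tissue as well as in time off doxycycline, differed from control in opposite directions in 4 lists. The difference itself is tumor against pre-tumor. A call in that comparison was a condition for picking these lists, so its adjusted p values are no separate support. Fatty acid oxidation lay 0.35 above all genes in pre-tumor liver and −1.06 in tumor (difference adjusted p = 1.79e-06, 0.170 with an estimated correlation). Fatty acid synthesis lay at 0.41 and −1.32 (adjusted p = 0.000103, and 0.187 with an estimated correlation). The interferon response lay at 0.27 and −1.98 (adjusted p = 2.34e-13, and 0.0405 with an estimated correlation) and the endothelium list at 0.53 and −0.57 (adjusted p = 1.70e-05, and 0.0485 with an estimated correlation). Against control itself, with an estimated correlation, none of the 4 lists was called in pre-tumor (adjusted p from 0.172 to 0.792) or in tumor (0.0660 to 0.376), so the opposite directions rest on the preset. Over 27 alternatives these differences had adjusted p of at most 0.000224, 0.00401, 6.18e-11 and 0.000396 in that order, but the pre-tumor calls of these lists ended with single arrays left out.

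Probes without a gene symbol, outside the gene test, held a signal too: 157 of 4019 changed in tumor against control, 84 of them higher. In pre-tumor against control 1 changed, which was lower. The counts were 236 in tumor against pre-tumor, 187 in regression against tumor and 53 in regression against control.

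Other splits of the same arrays into groups of the same sizes were counted, 35 per comparison. For the gene counts the real split gave more than any other in tumor against control (3164, highest other split 1455), tumor against pre-tumor (3702, highest other 312), regression against tumor (3254, highest other 0) and regression against control (1613, highest other 264). The splits take the arrays as independent samples, which the labels do not state, and their shares were not adjusted over the comparisons. In each of these comparisons 1 of 35 splits, the real one, gave as many, the smallest share possible. The same held for the reversed tumor changes (1702, highest other 0), but the other splits of regression against tumor called 0 genes and so could reverse none, which leaves this count untested. The split with 1455 genes set tumor 4 with the 3 controls against the other tumor arrays, and that with tumor 3 in its place gave 1404, whereas tumor 1 and tumor 2 in its place gave 2 and 0. The cause of so many calls was not tested. In pre-tumor against control 0 genes changed (highest other 14) and 0 changes were kept in tumor (highest other 7). All 35 splits match 0 by construction, so this says nothing about chance. Chance cannot be excluded for the 10 lists of that comparison (highest other 21, 24 splits gave as many). Tumor had 24 lists against control (26, 7 splits) and 23 against pre-tumor (29, 9). Regression had 26 against tumor (29, 5) and 22 against control (24, 3). In these, the other splits with as many moved at most 1 array per group, which keeps most of the contrast and cannot test chance.

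In regression, proliferation genes were lower than in tumor while oncofetal genes stayed high. More non-tumor liver in the regression samples would lower both alike. The 10 oncofetal genes raised in tumor had a median change of −0.30 (SD 1.57, 1 lower and 1 higher), against a mean of −2.64 for the cell cycle list, which argues against dilution as the whole cause. An effect of doxycycline itself cannot be told apart from MYC being switched off, since 0 of the 11 arrays outside regression came from mice put back on doxycycline. The loss of MYC expression may be the cause and stays open beside it.

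By the preset, several of the 8 marker lists of other cell types were called higher in regression than in control or in tumor, whereas those of B and plasma cells and of bile duct cells were called in neither and neutrophils against tumor alone. With an estimated correlation the calls were lost for neutrophils (adjusted p = 0.293) and T and NK cells (0.0920) against tumor, and for endothelium (0.171), T and NK cells (0.320) and erythroid cells (0.252) against control. A lower share of hepatocyte-lineage RNA would raise all 8 lists alike, but their shifts against control ran from 2.17 in macrophages and 2.00 in stellate cells to −0.48 in neutrophils, a variance of 0.914 where the highest of the others among 35 assignments gave 0.786 (exact permutation p = 0.0286, the smallest it can give). Against tumor all 8 lists rose, as a lower share would give, but by 1.81 in macrophages and 0.40 in B and plasma cells. The variance was 0.260 against 0.229 at most in the others among 70 assignments (exact permutation p = 0.0286, again the smallest it can give). This argues against a lower hepatocyte share as the whole cause in both comparisons, and a change in number or state of the cell types that rose may be the cause and stays open.

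1 Myc probe rose in tumor, and the other 2 did not pass against control. Array scaling or background is argued against for the probe that rose, since its smallest rise over 5 scalings was 3.28. A candidate explanation is that this probe reads RNA of the MYC transgene, which would make it higher in pre-tumor than in control arrays. It was, without overlap in the arrays (lowest pre-tumor 0.09, highest control −0.23), but with an exact permutation p of 0.0857, where 0.0286 was the smallest possible, and in regression it lay 0.50 from control (adjusted p = 0.605), so this stays open. The rule for this test first counted a p of 0.05 or more alone against the explanation, and was changed after the p was seen, since the arrays do not overlap.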

How the results depend on the processing

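The alternative without the 4 high-E1A arrays (control 1, pre-tumor 1, pre-tumor 4 and tumor 4) was chosen after seeing the data. The others were planned. The 4 arrays had a median E1A signal of 25.6 to 76.1, and the rest at most 10.4. What it says of array quality was not tested. The sex of the mice was not used as a covariate, because Xist and the Y-linked genes did not show both sexes. Of 22337 named-gene values under alternatives, 21475 kept their side of the threshold, 781 no longer passed and 78 passed. Another 3 reversed, counting called values alone. Causes of reversals and of counts changed over 1.5 times were not tested unless stated. After normexp correction there were 11 genes, 6 lists and 5 kept changes in pre-tumor against control, and Atic in regression against control was 0.01. The authors' table gave 3 genes and 2 kept changes there, quantile normalization 6 lists, the strict filter 6 lists, a trended robust variance 1 gene, and leaving out the 4 arrays 21 lists. With slide as a block regression against control had 990 genes. With replicate number as a block it had 3536, and pre-tumor against control 18 lists; residuals correlated at a median of 0.120 in same-number arrays (11 of 21 pairs over 0.1) and −0.036 in others (16 of 63), so an effect shared by number stays open. With the mean of probes, Pygl in regression against tumor was −0.57 and Fdft1 0.20, as other probes of these genes are averaged in. With an estimated correlation the comparisons had 0, 10, 12, 12 and 4 lists, where only the correlation used differs. With 1 array left out, pre-tumor against control had 0 to 3 genes, 3 to 16 lists and 0 to 1 kept changes, and regression against control 1027 to 1828 genes. The other counts stayed within 1.5 times: 2296 to 3489 genes in tumor against control, 2901 to 3949 in tumor against pre-tumor and 2422 to 3527 in regression against tumor. Signal over background limits genes seen on few arrays: from 46.4% to 90.8% of spots were well above background, and changes against a group without signal are bounds.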

Other observations

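All families and genes in this part were chosen after seeing the data, from 14 families taken by symbol.

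Beyond the lists above, chaperonin subunits, splicing factors and nuclear pore genes were higher in tumor than in control and lower in regression than in tumor, in part only by the preset. Of 10 chaperonin genes, which fold actin and tubulin, 8 rose in tumor against control and 9 fell in regression against tumor (medians 2.09 and −1.82 relative to all genes; adjusted p = 3.37e-06 and 6.86e-08, and 0.0545 and 0.0482 with an estimated correlation). Cct5 rose by 2.17 ± 0.33, fell by 2.30 ± 0.31 and then differed by −0.12 ± 0.33 from control (adjusted p = 0.862). Of 32 splicing factors 19 rose in tumor against control and 21 fell in regression against tumor (medians 1.52 and −1.23; adjusted p = 1.38e-12 and 4.91e-12, and 0.0545 and 0.0588 with an estimated correlation), and of 20 nuclear pore genes 13 and 11 (2.14 and −1.27; adjusted p = 4.16e-10 and 1.01e-08, and 0.0545 and 0.0482 with an estimated correlation). Srsf1 rose by 2.33 ± 0.41 and fell by 1.82 ± 0.38. Over 5 scalings the tumor medians stayed at or above 1.37 for chaperonins, 0.61 for splicing factors and 0.81 for nuclear pore genes. The regression medians ran from −1.89 to −1.38, −1.26 to −0.66 and −1.34 to −0.57 in that order.

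Mitochondrial ribosomal proteins rose in tumor (20 of 78, median 0.95, adjusted p = 4.72e-12, and 0.231 with an estimated correlation) and fell in regression (50 of 78, median −1.09, adjusted p = 6.10e-22, and 0.0814 with an estimated correlation). Over 5 scalings these medians ran from 0.50 to 0.95 and from −1.13 to −0.69. Of 5 major urinary protein genes, made by hepatocytes, 5 fell in tumor (median −8.09, adjusted p = 2.99e-08, and 0.0736 with an estimated correlation), 4 rose in regression, and 5 were still lower than in control. Cathepsin and lysosome membrane genes rose in regression against tumor (12 of 40, with 1 lower; median 0.66, adjusted p = 1.52e-06, and 0.0588 with an estimated correlation), as did collagens (12 of 41; median 0.40, adjusted p = 0.000734, and 0.0780 with an estimated correlation). Over 5 scalings the medians ran from 0.31 to 0.70 for cathepsins and from 0.12 to 0.40 for collagens. Lipoprotein lipase, Lpl, differed by 0.03 ± 0.41 in tumor against control (adjusted p = 0.971) and rose by 2.42 ± 0.38 in regression against tumor (adjusted p = 0.000436). The leukocyte integrin gene Itgb2 rose by 2.05 ± 0.45 (adjusted p = 0.00493).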
